A study of Mus musculus with 4 samples.

How the data were processed

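RNA sequencing was done on 4 libraries of cultured mouse leukaemia cells, 2 labelled WT and 2 labelled Tet2 KO. Per the labels' protocols, RNA was extracted with QIAzol and libraries were made with a stranded mRNA kit. Reads were processed with STAR and RSEM on the mm10 build, per the submitters' processing notes, which give no versions. The annotation release and the filters are not given in the sources used here. The authors deposited 1 table of TPM, with 24589 rows, 1 column per library and 2 decimals. Every column summed to the same total within rounding, spike-ins included. TPM keep no depth, so no count, interval or floor was computed, and a value of 0 means only that a gene was listed at 0. Because TPM are shares of a fixed total, a change in abundant transcripts or spike-ins moves all other values.

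The table held 92 ERCC spike-in rows, which took 4.38 and 4.43% of the WT libraries and 5.48 and 5.33% of the Tet2 KO libraries. They were left out of the tests. Another 27 rows carried date-like names of the kind spreadsheet software makes from gene symbols. They took 0.103 to 0.122% of the total, were tested and counted as genes, and were not named. The reads of near-identical genes may have been divided between copies by the quantification. Such genes are marked as uncertain where they were recognised, and others may be unmarked. Gene positions and transcript lengths were taken from GENCODE M21 on the same build, which matched 98.4% of gene rows by symbol or synonym.

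The 2 groups were compared with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, on log2(TPM + 1), with an intensity trend and robust variance estimation, for genes of at least 1 TPM in at least 2 libraries. This is the test fixed for TPM before the data were examined. Adjusted p-values are Benjamini-Hochberg over the 11452 genes tested, two-sided, with a threshold of 0.05. Fold changes named as log2 are on the log2(TPM + 1) scale, which understates the change of low genes, and folds named without log2 are ratios of mean TPM. Named genes followed a rule fixed beforehand: 9 genes chosen from the study's subject (Tet2, Nras, Tspan13, Cxcr4, Cd274, Meis1, Hoxa9, Kit and Myc), the 12 largest rises and the 12 largest falls in log2 fold change past the threshold with both libraries of a group apart from the other group and a mean of at least 5 TPM in the higher group (leaving out predicted genes and small RNAs), and up to 4 called members of each of 33 gene lists. The lists covered engineered loci, DNA and RNA methylation, self-renewal, homing, myeloid programmes, immunity, interferon, proliferation, signalling, metabolism, other blood, stromal and sex-linked markers, and neighbours of Tet2. The 28 lists with at least 5 tested genes were tested with camera in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists.

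The steps were tested on simulated data for this comparison with 11452 genes. Of 100 genes changed by 0.5 on the log2 scale 85 were recovered, and of 100 genes changed by 1 all 100 were, with 12 false calls (6.09% of calls). A list of 25 genes shifted by 0.5 was called, and 0 of 20 unshifted lists were. The simulated noise was independent between genes, and few genes were changed. In the data 8463 genes were called, the median of all genes moved by 0.228 and genes of a list can be correlated. The simulated rates of false calls may therefore be too low for these data. Alternatives fixed beforehand were a replicate block, pseudocounts of 0.1 and 5, no filter or a filter of 5 TPM, median-ratio scaling, quantile normalization, limma without trend or without robust estimation, leaving out each library, an estimated correlation and fry. Scaling to the spike-ins, leaving out the spike-in rows, and median-ratio scaling with a correction for transcript length and GC content (99.2% of tested genes had both) were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.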

Results

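Gene expression was measured by RNA sequencing in mouse acute myeloid leukaemia cells that carried NRAS and AE9a, a short splice form of the AML1-ETO fusion oncoprotein. The cells had been made from bone marrow haematopoietic stem cells of wild-type (WT) mice or of Tet2-/- mice, in which exon 3 of Tet2 is deleted. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine. The cells were grown with stem cell factor at 50 ng/ml, IL-3 and IL-6 at 10 ng/ml each, G418 at 1 mg/ml and puromycin at 2 µg/ml. There were 2 WT and 2 Tet2 KO libraries, and every mean below is over n = 2 libraries with its SD. Values were deposited as TPM, transcripts scaled to a fixed total, which keep no sequencing depth, so the depth of each library is unknown. Between 14753 and 15139 genes were above 0 TPM in a library, and 11452 genes reached 1 TPM in at least 2 libraries and were tested. Replicates lay close together: among 7941 genes averaging at least 10 TPM, the median absolute log2 difference was 0.0504 between the WT libraries and 0.0716 between the Tet2 KO libraries. It was 0.33 to 0.354 between libraries of different genotype. These differences are on the deposited scale, so those between genotypes include a general shift, a median log2 fold change of 0.228 over all genes. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

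The targeted gene was listed at nearly the same level in all libraries. Tet2 (chromosome 3, 133463679 to 133545139, mm10) stood at 16.62 and 16.98 TPM in WT and at 16.98 and 16.95 TPM in Tet2 KO. The fitted log2 fold change was 0.01 (SE 0.0685, limma adjusted p = 0.868). Exon 3 (133485512 to 133488717) holds 3206 of the 9179 bases of the longest annotated coding transcript, or 34.9%, and its reads were not separated from those of the other 10 exons. The gene-level value therefore does not check the deletion. Relative to the median of all genes, Tet2 was lower in Tet2 KO, with a log2 fold change of -0.22 (limma adjusted p = 0.00935), and relative to the spike-in RNAs of -0.21 (limma adjusted p = 0.0325). Over the alternatives run, its adjusted p ranged from 5.23e-05 to 0.992. Of the other engineered loci, Nras, which encodes the small GTPase, fell from 109.07 ± 0.735 to 94.7 ± 1.71 TPM (limma adjusted p = 0.0011). Runx1, which encodes a haematopoietic transcription factor, rose from 56.3 ± 0.509 to 102.02 ± 0.0849 TPM. Endogenous and introduced transcripts of these genes were not told apart. Runx1t1 was at 35.93 and 37.20 TPM in WT and at 37.77 and 40.68 TPM in Tet2 KO, and did not pass the test (limma adjusted p = 0.15), but was lower relative to the median of all genes (-0.14, limma adjusted p = 0.034).

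Genes changed in both directions. Tet2 KO cells had higher RNA of the stem cell factor receptor Kit, of Meis1 and of genes of the stress and amino acid response. They had lower RNA of most tested neutrophil granule, monocyte and macrophage, cholesterol synthesis, glycolysis and respiratory chain genes. As lists, these and the stress response passed camera with the preset correlation. None of them did with an estimated correlation (adjusted p = 0.318 to 0.423), a setting with little power at 4 libraries. Of the 11452 genes tested, 6225 were higher and 2238 lower in Tet2 KO at an adjusted p under 0.05 in limma, and 698 and 321 of them changed at least 2-fold. At 2-fold the balance turned to 441 higher and 504 lower after median-ratio scaling, and the total of 1019 became 465 with a pseudocount of 5 and 1464 with a pseudocount of 0.1. The median log2 fold change of all genes was 0.23. When the libraries were rescaled by the median ratio, which brings this median near 0, 3815 genes were higher and 3936 lower, a share of 49.2% higher in place of 73.6%. Of the genes higher on the deposited scale, 45 were lower after rescaling, which moves all genes down by about the same amount. Changes relative to the median of all genes are given below wherever they alter a count or a call.

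**Figure D1:**
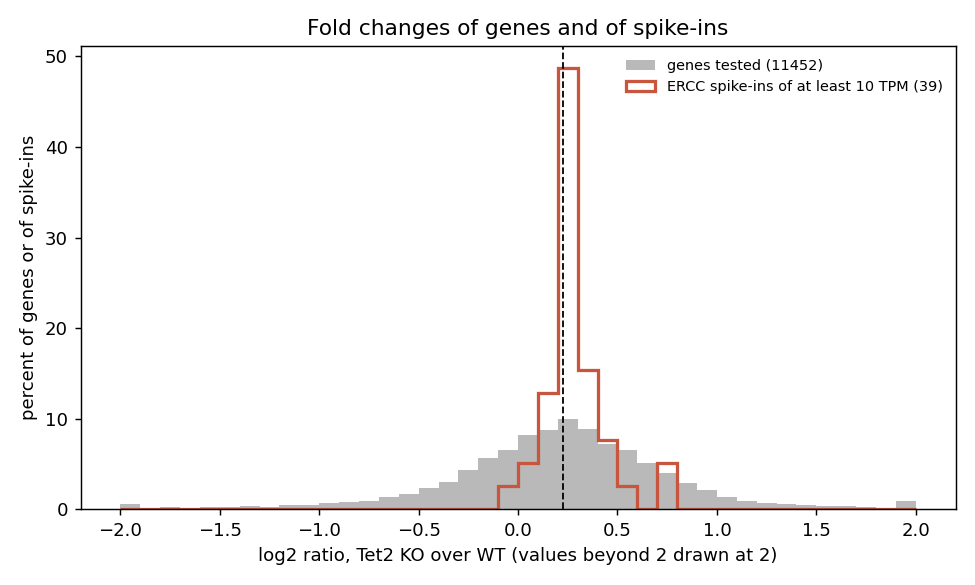
Distribution of log2 ratios, Tet2 KO over WT, for the 11452 genes tested (grey, log2 of TPM + 1) and for the 39 ERCC spike-in RNAs averaging at least 10 TPM (red outline), as a percentage of each set. The dashed line marks the gene median at 0.228, and the spike-in median lies at 0.258.

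Among the largest rises was Kit (chromosome 5, 75574916 to 75656722), from 11.8 ± 0.255 to 205.3 ± 5.81 TPM, a 17.4-fold difference in mean TPM. Gzmb, which encodes the cytotoxic granule protease granzyme B, rose from 15.1 ± 1.36 to 260.6 ± 7.67 TPM. Trib3, a pseudokinase gene induced by the integrated stress response, rose from 18.45 ± 0.523 to 223.2 ± 11.2 TPM, the neutrophil chemokine gene Cxcl3 from 13.7 ± 0.629 to 197.9 ± 21.5 TPM, and Npl, which encodes N-acetylneuraminate lyase, from 32.7 ± 1.301 to 281.1 ± 2.71 TPM. Trp53i11, Tns1, Akap2, Cd59a and Cbx6 lay below 2 TPM in WT and between 13.2 and 25.8 TPM in Tet2 KO. Xlr was listed at 0 in both WT libraries and averaged 6.56 TPM in Tet2 KO. It belongs to a family of similar copies, so its value is uncertain. BC064078 rose from 2.51 ± 1.41 to 47.9 ± 4.93 TPM (limma adjusted p = 0.0129), a call that was lost without either Tet2 KO library (limma adjusted p = 0.0774 and 0.0792, range over alternatives 3.75e-28 to 0.0792).

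On the log2(TPM + 1) scale, the largest fall of a named gene was that of Lpl (chromosome 8, 68880491 to 68907448), which encodes lipoprotein lipase, from 470.4 ± 15.8 to 32.4 ± 0.424 TPM, 14.5-fold. Ckb, the brain-type creatine kinase gene, fell from 36.2 ± 1.29 to 2.03 ± 0.156 TPM, and Acvrl1, a receptor gene of the TGF-beta family, from 143.8 ± 3.02 to 16.7 ± 1.65 TPM. Itgax, the gene of the integrin CD11c, fell from 86.4 ± 0.0919 to 10.4 ± 1.12 TPM, Cd74, the invariant chain gene, from 242.7 ± 5.51 to 32.6 ± 1.49 TPM, and Arg1, the arginase gene, from 33.9 ± 1.98 to 3.22 ± 0.926 TPM. Olr1, Angptl2, Hao1 and Psma8 fell between 8.13-fold and 41.8-fold. Ear2, an eosinophil ribonuclease gene, averaged 9.78 TPM in WT and was listed at 0 in both Tet2 KO libraries. This gene too has similar copies, so its value is uncertain. Ass1, which encodes argininosuccinate synthase, fell from 53.1 ± 8.79 to 5.27 ± 2.18 TPM (limma adjusted p = 0.0166), a call that was lost without either WT library (limma adjusted p = 0.119 and 0.123, range over alternatives 1.92e-07 to 0.123).

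**Figure D2:**
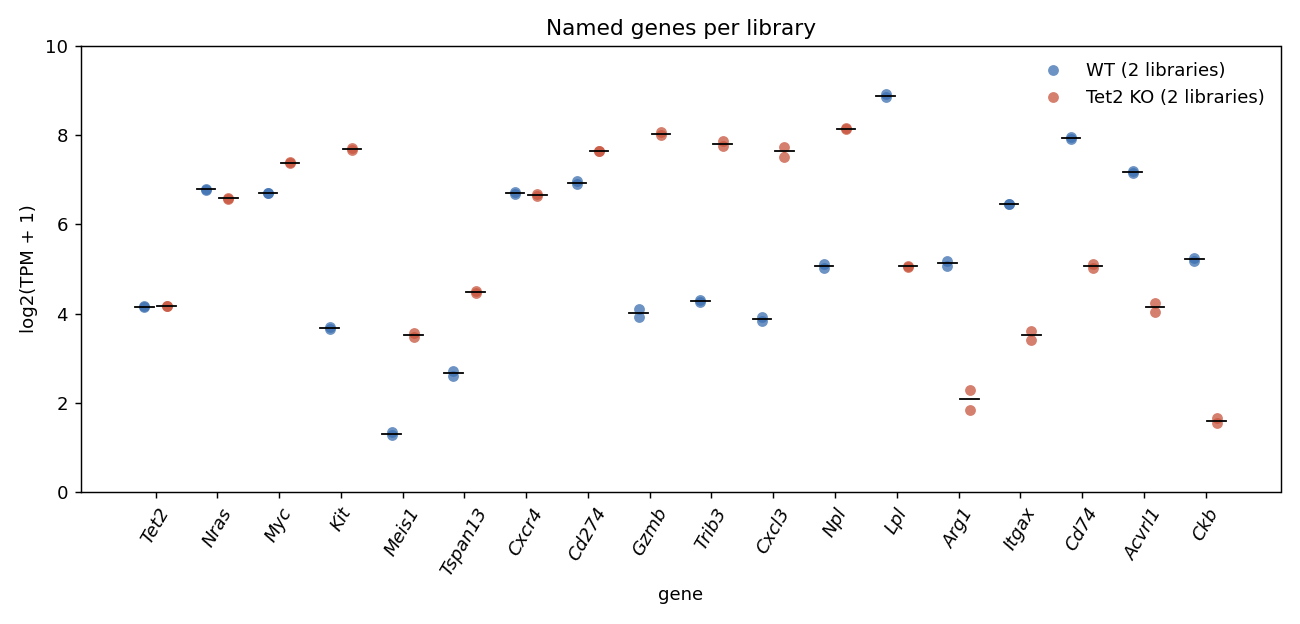
Level of 18 named genes as log2(TPM + 1) in each of the 2 WT (blue) and 2 Tet2 KO (red) libraries, with the log2 of the mean TPM + 1 as a short line. Tet2 lies at nearly the same level in all libraries, whereas the libraries of each group lie close together for Kit (11.8 against 205.3 TPM) and Lpl (470.4 against 32.4 TPM).

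The series title names leukaemia stem cell self-renewal, and the lists below were fixed before the data were examined. Of the 19 tested genes of the self-renewal list, 16 rose and 3 fell (median log2 fold change 0.79), and 15 rose and 4 fell relative to the median of all genes. The list passed camera (adjusted p = 0.0225, and adjusted p = 0.423 with an estimated correlation), and not when Tet2 KO replicate 1 was left out (adjusted p = 0.0533), when genes under 5 TPM were left out (adjusted p = 0.0742) or with no filter (adjusted p = 0.0623). Its adjusted p ranged over alternatives from 0.00114 to 0.423. Beside Kit, Meis1, a homeobox cofactor of leukaemic stem cells, rose from 1.48 ± 0.099 to 10.4 ± 0.544 TPM, the chromatin gene Hmga2 from 0.795 ± 0.00707 to 4.68 ± 0.297 TPM, and Mycn from 0.14 ± 0.099 to 2.46 ± 0.368 TPM. Hoxa9 was listed at 0 in all libraries. The homing and niche adhesion list moved both ways, with 10 of 19 members higher and 8 lower, turning to 7 higher and 9 lower relative to the median of all genes, and did not pass (camera adjusted p = 0.304). In it, Tspan13, a tetraspanin gene, rose from 5.32 ± 0.375 to 21.4 ± 0.622 TPM and the sphingosine 1-phosphate receptor gene S1pr1 from 3.95 ± 0.0636 to 16.9 ± 1.05 TPM. Cd44 fell from 166.9 ± 5.04 to 62.2 ± 2.47 TPM. The chemokine receptor gene Cxcr4 was at 102.8 ± 2.02 and 99.99 ± 1.4 TPM (log2 fold change -0.04, limma adjusted p = 0.455), and was lower relative to the median of all genes (-0.28, limma adjusted p = 4.67e-04, range over alternatives 4.67e-04 to 0.83).

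Most neutrophil granule and monocyte and macrophage genes fell, and some rose. Of the 21 tested genes of the neutrophil granule list, 16 fell and 5 rose, with a median log2 fold change of -0.90 (camera adjusted p = 3.46e-08, and adjusted p = 0.318 with an estimated correlation), and the same numbers relative to the median of all genes. Ngp, a secondary granule gene, fell from 851.8 ± 27.1 to 176.04 ± 3.26 TPM, Anxa1 from 961.3 ± 0.82 to 284.1 ± 2.68 TPM, the neutrophil elastase gene Elane from 38.2 ± 1.35 to 10.8 ± 0.212 TPM and Ms4a3 from 399.5 ± 13.2 to 134.2 ± 1.18 TPM. Of the 21 tested genes of the monocyte and macrophage list, 14 fell and 6 rose (camera adjusted p = 8.08e-06, and adjusted p = 0.318 with an estimated correlation). After median-ratio scaling 16 fell and 5 rose. Ctss, a lysosomal cathepsin gene, fell from 499.02 ± 8.096 to 128.1 ± 6.4 TPM, the mannose receptor gene Mrc1 from 25.8 ± 0.375 to 6.28 ± 0.587 TPM and Lyz1 from 8.01 ± 0.438 to 2.45 ± 1.02 TPM. The lysozyme gene Lyz2 fell from 19235 ± 5.71 to 7614 ± 54.8 TPM, and was not called after quantile normalization (log2 fold change -0.38, limma adjusted p = 0.342, range over alternatives 2.34e-28 to 0.342). Lyz1 is a close copy of the far more abundant Lyz2, so the value of Lyz1 is uncertain. Markers of other blood cells moved in both directions. Of the 15 tested mast cell and basophil markers, 6 rose and 7 fell (8 fell when adjusted over the list alone and 8 relative to the median of all genes, camera adjusted p = 0.256). Hpgds rose from 25.96 ± 1.52 to 101.3 ± 2.2 TPM and Il1rl1 from 33.2 ± 0.573 to 99.9 ± 1.05 TPM. The protease genes Cma1 and Mcpt8 fell, from 26.4 ± 1.42 to 4.93 ± 0.969 TPM and from 275.6 ± 9.03 to 84.1 ± 2.11 TPM. Of 10 tested megakaryocyte markers, 9 rose and 1 fell (camera adjusted p = 0.0347, adjusted p = 0.423 with an estimated correlation, and adjusted p = 0.159 with no filter on low values, range over alternatives 7.35e-05 to 0.423). After median-ratio scaling 8 rose and 1 fell. Pf4 rose from 12.5 ± 2.01 to 70.04 ± 1.88 TPM, Ppbp from 0.775 ± 0.474 to 6.46 ± 1.004 TPM and Nrgn from 4.78 ± 1.08 to 22.6 ± 0.53 TPM. Treml1 fell from 3.46 ± 0.0707 to 0.445 ± 0.00707 TPM.

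The other lineage lists held few tested genes. Of 6 erythroid markers, 5 rose and 1 fell (camera adjusted p = 0.0811, and adjusted p = 0.0187 relative to the median of all genes, adjusted p = 0.439 with an estimated correlation, range over alternatives 0.00574 to 0.439), with Cited4 up from 0.525 ± 0.00707 to 6.53 ± 1.83 TPM and Car2 from 10.1 ± 0.983 to 35.2 ± 0.311 TPM. Hbb-b2 and Hbb-bt had identical values in every library, and the list counts these near-identical copies as 2 genes. Of 6 T and NK cell markers, 4 rose and 2 fell (camera adjusted p = 0.724), among them Gzmb up and Il7r down from 66.02 ± 3.55 to 16.2 ± 0.163 TPM. Of 5 dendritic cell markers, 2 rose and 3 fell, or 1 and 3 relative to the median of all genes (camera adjusted p = 0.0839), with the lectin gene Clec10a up from 16.8 ± 1.29 to 129.9 ± 2.16 TPM and Itgax down. Of 4 eosinophil markers, 1 rose and 3 fell, of 3 stromal and endothelial markers 1 rose and 1 fell (1 and 2 relative to the median of all genes), and the 1 tested B cell marker, Cd22, fell from 2.59 ± 0.0566 to 0.6 ± 0.24 TPM. Pdgfrb rose from 4.63 ± 0.0495 to 17.2 ± 0.714 TPM and Pecam1 fell from 262.6 ± 1.67 to 172.5 ± 4.98 TPM. These 3 lists were too short for the list test.

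The title also names tumour immunity. Of 27 tested immune checkpoint and suppressor genes, 15 fell and 8 rose (camera adjusted p = 3.86e-04, and adjusted p = 0.423 with an estimated correlation). Relative to the median of all genes 17 fell and 6 rose. The members that moved include ligands that rose: Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), went from 121.1 ± 4.05 to 199.02 ± 0.219 TPM, and Pdcd1lg2, which encodes PD-L2, from 13.9 ± 0.00707 to 51.2 ± 1.15 TPM. Arg1 fell, as did Lgals3, the galectin-3 gene, from 2279 ± 12.4 to 816.2 ± 5.14 TPM, and the costimulatory gene Cd86 from 2.97 ± 0.198 to 0.58 ± 0.0283 TPM. In the MHC class II list, 6 of 12 tested genes fell and 5 rose, or 6 and 2 relative to the median of all genes (camera adjusted p = 0.0389, and adjusted p = 0.423 with an estimated correlation). The call was lost relative to the median of all genes (adjusted p = 0.149) and without WT replicate 1 (adjusted p = 0.101) or WT replicate 2 (adjusted p = 0.0991), and its adjusted p ranged over alternatives from 0.0154 to 0.618. Cd74 fell, as did H2-Aa from 4.77 ± 0.247 to 0.28 ± 0.269 TPM and H2-Eb1 from 1.79 ± 0.134 to 0.08 ± 0.113 TPM. H2-Ob, which encodes a chain of the class II modulator H2-O, rose from 0.985 ± 0.0636 to 5.09 ± 0.0778 TPM. In the MHC class I list 12 of 21 genes rose and 5 fell, but 6 rose and 10 fell relative to the median of all genes, and the list did not pass (camera adjusted p = 0.94). The peptide transporter genes Tap1 and Tap2 rose to 31.6 ± 1.07 and 92.9 ± 5.3 TPM from 17.3 ± 1.4 and 58.5 ± 1.56 TPM, and Nlrc5, the class I transactivator, from 4.31 ± 0.247 to 8.23 ± 0.629 TPM. H2-Q4, a member of a family of near-identical copies, rose from 9.34 ± 1.38 to 22.5 ± 2.72 TPM, and this value is uncertain.

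Of the 26 tested type I interferon response genes, 18 rose and 2 fell, or 11 and 5 relative to the median of all genes (camera adjusted p = 0.203). With the length and GC correction the list passed (adjusted p = 0.0357, range over alternatives 0.0357 to 0.423), and it did not pass with an estimated correlation (adjusted p = 0.423). Rtp4 rose from 1.94 ± 0.311 to 8.7 ± 0.311 TPM, Rsad2 from 3.82 ± 0.156 to 10.9 ± 0.848 TPM, Oasl2 from 2.6 ± 0.58 to 6.47 ± 0.0778 TPM and Trim30a from 21.8 ± 1.38 to 36.6 ± 2.79 TPM. Of 16 interferon gamma response genes, 10 rose and 1 fell, or 8 and 3 relative to the median of all genes (camera adjusted p = 0.27), with the near-identical pair Tgtp1 and Tgtp2 at 1.45 and 17.2 TPM in Tet2 KO against 0.185 and 5.12 TPM in WT, and Gbp8 up from 0.29 ± 0.0141 to 2.19 ± 0.283 TPM. Inflammatory cytokine and NF-kB genes split evenly, with 12 of 26 higher and 12 lower, or 8 and 14 relative to the median of all genes (camera adjusted p = 0.0618, direction down, with a median of -0.09 and a mean of 0.13). Cxcl2 rose from 62.6 ± 1.803 to 173.4 ± 4.04 TPM and Nfkbiz from 12.3 to 38.4 TPM. Il13 fell from 4.57 ± 0.304 to 0.64 ± 0.156 TPM. Of 13 NK cell and cytotoxic ligands, 5 rose and 7 fell, or 2 and 7 relative to the median of all genes (camera adjusted p = 0.0625). Raet1e fell from 3.28 ± 0.82 to 0.95 ± 0.0141 TPM, Tnfsf4 from 6.06 ± 0.757 to 2.56 ± 0.721 TPM and Raet1d from 8.68 ± 0.841 to 5.16 ± 1.08 TPM. H60b rose from 0.885 ± 0.219 to 1.94 ± 0.318 TPM. Raet1d and Raet1e belong to a family of close copies, so their values are uncertain.

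**Figure D3:**
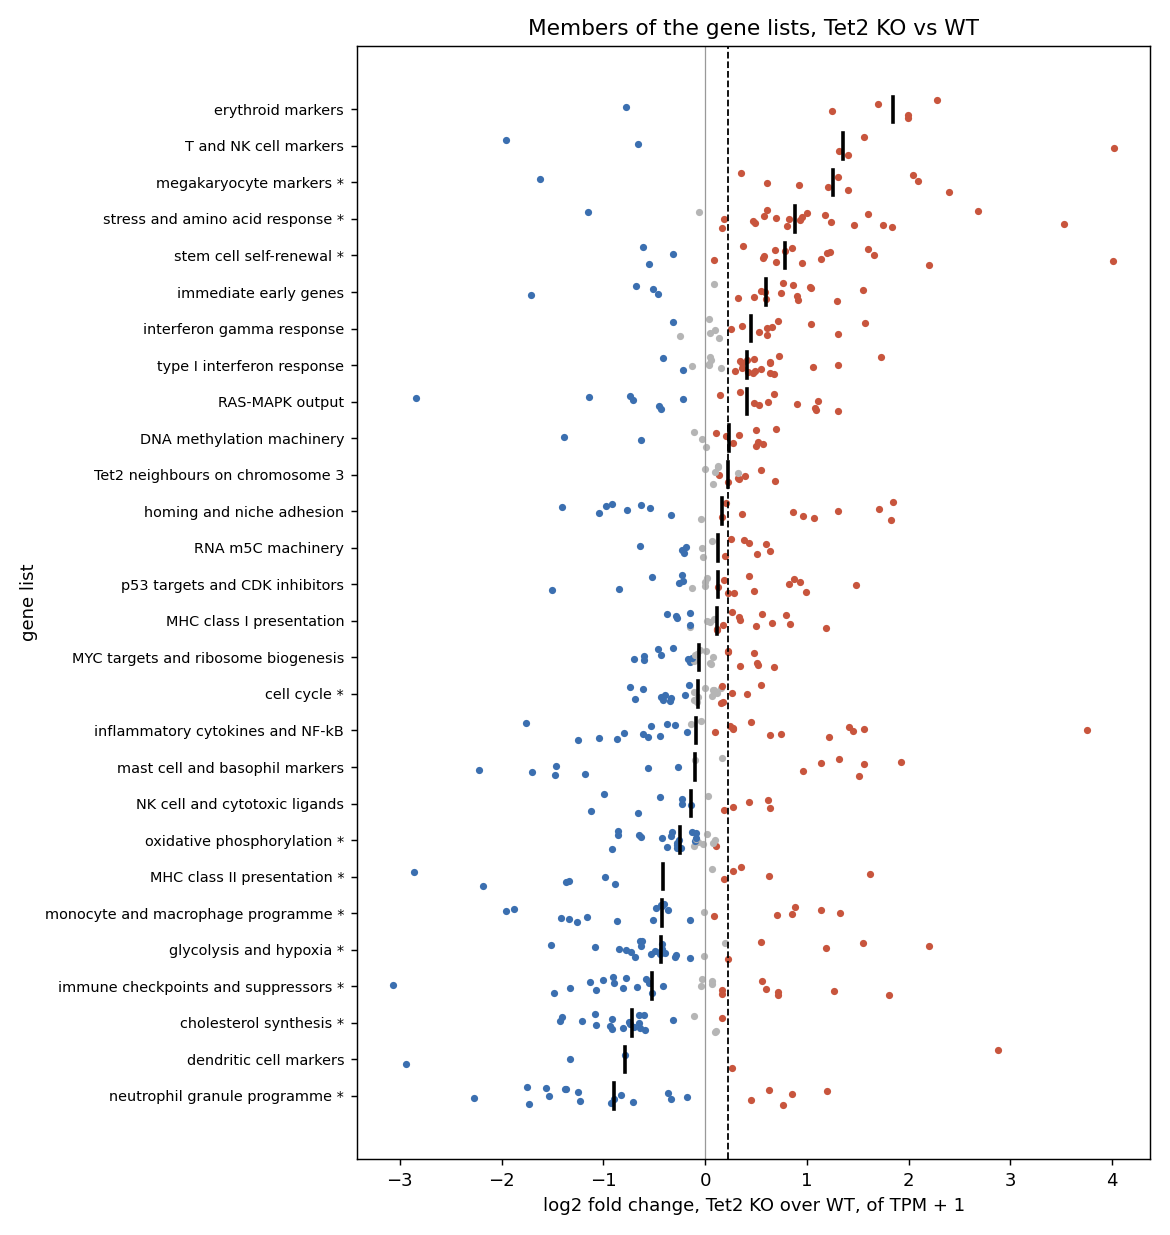
Log2 fold change of TPM + 1, Tet2 KO over WT, of each tested member of the 28 gene lists with at least 5 tested genes. Red points rose and blue points fell at an adjusted p under 0.05 in limma, grey points did not pass, black bars are list medians, the dashed line is the median of all genes at 0.228, and asterisks mark the 11 lists past the camera threshold with the preset correlation.

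Most tested cholesterol synthesis, respiratory chain and glycolysis genes fell, and some glycolysis and hypoxia genes rose. In the cholesterol synthesis list 18 of 22 genes fell and 1 rose (2 rose when adjusted over the list alone), with a median log2 fold change of -0.72 (camera adjusted p = 7.24e-11, and adjusted p = 0.318 with an estimated correlation). In all, 21 fell and 0 rose relative to the median of all genes. Fdps, which encodes farnesyl diphosphate synthase, fell from 156.2 ± 0.481 to 57.7 ± 1.58 TPM, Mvk, the mevalonate kinase gene, from 11.2 ± 0.643 to 4.3 ± 0.304 TPM and Hsd17b7 from 10.5 ± 0.898 to 4.4 ± 0.446 TPM. Of 26 genes of oxidative phosphorylation, 18 fell and 1 rose (camera adjusted p = 3.46e-08, and adjusted p = 0.423 with an estimated correlation), and all 26 were lower relative to the median of all genes. The list median on that scale was -0.488, and -0.289 with the length and GC correction. Ndufa4 fell from 466.5 ± 16.9 to 247.8 ± 10.1 TPM, and Atp5g1, Cox7a2 and Cox6c fell by 1.82-fold, 1.82-fold and 1.58-fold. Of 26 glycolysis and hypoxia genes, 19 fell and 5 rose, or 20 and 4 relative to the median of all genes (camera adjusted p = 6.57e-07, and adjusted p = 0.423 with an estimated correlation). Egln3, a prolyl hydroxylase gene, fell from 35.1 ± 1.53 to 11.7 ± 0.339 TPM. Against the direction of the list, the angiogenic factor gene Vegfa rose from 7.65 ± 0.297 to 38.7 ± 0.141 TPM, Ndrg1 from 86.2 ± 3.17 to 254.8 ± 3.59 TPM and the glucose transporter gene Slc2a3 from 32.1 ± 0.318 to 74.5 ± 2.07 TPM. In the stress and amino acid response list 20 of 22 genes rose and 1 fell, or 18 and 2 relative to the median of all genes (median 0.88, camera adjusted p = 8.47e-05, and adjusted p = 0.423 with an estimated correlation). With Trib3, the mitochondrial folate gene Aldh1l2 rose from 0.725 ± 0.134 to 10.05 ± 0.247 TPM, the transcription factor gene Ddit3 from 44.7 ± 0.283 to 162.6 ± 8.66 TPM and Chac1 from 5.73 ± 0.502 to 21.7 ± 2.61 TPM.

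In the cell cycle list 10 of 27 genes fell and 6 rose, and 20 fell and 2 rose relative to the median of all genes (camera adjusted p = 0.011, and adjusted p = 0.423 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell from 103.7 ± 0.311 to 61.6 ± 1.004 TPM, Plk1 from 63.5 ± 2.89 to 38.97 ± 0.354 TPM and Ccne1 from 28.1 ± 0.41 to 18.1 ± 0.863 TPM, and the mitotic kinesin gene Kif11 rose from 41.05 ± 0.559 to 60.6 ± 0.113 TPM. Myc rose from 103.3 ± 0.304 to 165.8 ± 2.77 TPM, yet in the list of MYC targets and ribosome biogenesis 9 of 24 genes fell and 7 rose (camera adjusted p = 0.0618). Myc itself is a member of this list and counts among those that rose, on either scale. Relative to the median of all genes 17 fell and 5 rose (adjusted p = 0.0119, adjusted p = 0.423 with an estimated correlation, range over alternatives 0.00542 to 0.423). Nme1, Odc1 and Bop1 fell by 1.62-fold, 1.52-fold and 1.53-fold. Of 18 RAS-MAPK output genes, 11 rose and 7 fell, or 9 and 8 relative to the median of all genes (camera adjusted p = 0.658). Cyclin D1, Ccnd1, fell from 53.6 ± 1.87 to 6.61 ± 0.544 TPM and Fosl1 from 6.995 ± 1.02 to 2.65 ± 0.792 TPM. Dusp4 rose from 45.01 ± 0.495 to 113.2 ± 3.8 TPM and Etv1 from 0.93 ± 0.0283 to 3.18 ± 0.354 TPM. Of 19 immediate early genes, 14 rose and 4 fell (15 rose when adjusted over the list alone, camera adjusted p = 0.106, and adjusted p = 0.035 relative to the median of all genes, adjusted p = 0.595 with an estimated correlation, range over alternatives 0.00864 to 0.595). On that scale 13 rose and 5 fell. Fos rose from 155.02 ± 5.72 to 382.8 ± 7.21 TPM, Dusp2 from 42.8 ± 1.11 to 127.2 ± 3.62 TPM and Nr4a1 from 17.7 ± 0.764 to 37.4 ± 2.06 TPM. Egr2 fell from 19.5 ± 0.0636 to 5.27 ± 0.177 TPM. Of 21 p53 targets and CDK inhibitors, 11 rose and 6 fell, turning to 6 and 11 relative to the median of all genes (camera adjusted p = 0.658). Cdkn2a fell from 121.7 ± 6.89 to 42.3 ± 0.311 TPM. Bbc3 rose from 11.3 ± 0.841 to 33.4 ± 1.28 TPM, Cdkn1b from 16.2 ± 0.212 to 33.2 ± 2.93 TPM and Sesn2 from 30.9 ± 1.55 to 59.9 ± 5.75 TPM.

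Of 14 tested genes of the DNA methylation machinery, 9 rose and 2 fell, and 4 rose and 6 fell relative to the median of all genes (camera adjusted p = 0.948). Idh1, which encodes the cytosolic isocitrate dehydrogenase that makes the TET cosubstrate 2-oxoglutarate, fell from 175.9 ± 4.53 to 66.5 ± 1.1 TPM, and Dnmt3l from 10.04 ± 0.311 to 6.15 ± 0.0495 TPM. The maintenance methyltransferase gene Dnmt1 rose from 100.9 ± 2.48 to 150.7 ± 7.82 TPM. Of 14 genes of the RNA m5C machinery, 7 rose and 4 fell, turning to 4 and 6 relative to the median of all genes (camera adjusted p = 0.519), with Ybx1 down from 791.7 ± 5.19 to 507.96 ± 15.2 TPM and Nsun6, Mbd5 and Nsun4 up 1.79-fold, 1.6-fold and 1.5-fold. The call of Mbd5 was lost with scaling to the median and correction for transcript length and GC content (limma adjusted p = 0.372, range over alternatives 2.87e-06 to 0.372). Of 13 tested neighbours of Tet2 on chromosome 3, 7 rose and 0 fell (6 rose when adjusted over the list alone, camera adjusted p = 0.329), and 3 rose and 2 fell relative to the median of all genes. Gstcd rose from 11.3 ± 0.559 to 18.7 ± 0.346 TPM and Nfkb1 from 65.8 ± 0.453 to 97.2 ± 7.58 TPM. Cenpe and Aimp1 rose 1.32-fold and 1.26-fold on the deposited scale, but Aimp1 was not called relative to the median (limma adjusted p = 0.139, range over alternatives 3.08e-06 to 0.173) and Cenpe turned lower with the length and GC correction (log2 fold change -0.155, limma adjusted p = 0.0147, range 7.33e-06 to 0.0621). All 4 tested Y-linked genes were higher in Tet2 KO. Uty rose from 8.3 ± 0.693 to 15.5 ± 1.87 TPM, Ddx3y from 22.6 ± 1.46 to 39.8 ± 4.34 TPM and Kdm5d from 11.3 ± 0.566 to 17.8 ± 0.636 TPM, the last with no call after the length and GC correction (limma adjusted p = 0.196, range 9.29e-08 to 0.196), and Eif2s3y, from 91.8 ± 3.5 to 109.2 ± 4.32 TPM, was not called relative to the median of all genes (limma adjusted p = 0.942, range 1.14e-04 to 0.942).

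In all, 11 of 28 lists passed camera, 3 of them up and 8 down. With a correlation estimated from the data 0 lists passed (lowest adjusted p = 0.318), and 3 had an unadjusted p under 0.05. That setting takes its degrees of freedom from the 4 libraries and has little power. The cholesterol synthesis list had an estimated correlation of -0.0368, below the preset 0.01. Its unadjusted camera p still went from 2.59e-12 to 0.0164. The lost calls therefore do not show that correlation between genes made the list results, and their strength stays open. The directional test fry, which compares each list with no change and not with the other genes, called 23. Its direction turned from up to down after median-ratio scaling for the DNA methylation, RNA m5C, homing, MHC class I, inflammatory, p53 and RAS-MAPK lists. The DNA methylation, RNA m5C, homing, p53 and RAS-MAPK lists had a median above 0 and a camera direction of down. Their means lay below the mean of the other genes. Adjusted over the list alone, the number of called members equalled that over all genes in 29 of the 33 lists.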

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

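The tests of the spike-in scale, the macrophage share and Tet2 exon 3, and the spike-in and length-corrected scalings, were chosen after the results they measure had been seen. The others were written beforehand.

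The ERCC spike-in RNAs, which were left out of the gene tests, took a mean of 54041 TPM in Tet2 KO and 44008 TPM in WT. They stood out as a signal outside the main measurement that was higher than in the control libraries. More genes were called higher than lower in Tet2 KO, and this pattern was weighed against the scale of the libraries. The median log2 ratio of the 39 spike-ins averaging at least 10 TPM was 0.258, within 0.1 of the gene median of 0.228, and 38 of them were higher in Tet2 KO. A shift of scale shared by spike-ins and genes would give this excess of higher calls, but it restates these medians. In a fixed total it needs other transcripts to take a smaller part. It is thus no separate cause from a loss in other transcripts. Single spike-ins differed between the 2 Tet2 KO libraries, and not all in the same direction. ERCC-00046 stood at 5803 TPM in replicate 1 and 4140 TPM in replicate 2, and ERCC-00002 at 12429 and 14177 TPM. The size of a scaling to the spike-ins is thus uncertain. Leaving out the 164 genes of at least 1000 TPM and rescaling still left a median of 0.145 (bootstrap SD 0.00484), above the limit of 0.1. These genes include some that fell, such as Lyz2 (19235 to 7614 TPM), and some that rose, such as Eef1a1 (9248 to 14783 TPM). The 10 highest genes in WT took 13.4% of each WT library and 7.65 and 7.56% of the Tet2 KO libraries. All 164 took 45 and 44.6%, and 40.4 and 40.2%. Because rising genes were left out too, the test cannot decide whether a few falling abundant genes were the cause. The 164 abundant genes together took a smaller part in Tet2 KO, which left a larger part to spike-ins and other genes. How much of the shift this accounts for stays open. How the spike-ins were added is not given in the sources used here.

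Most macrophage genes were lower and Kit was higher in Tet2 KO. Relative to the median of all genes, 0 of 14 macrophage list members averaging at least 20 TPM in WT rose, but 5 of all 21 tested members did. The log2 falls of the 14 were unequal, from -0.154 for Adgre1 to -2.2 for Ctss. A lower share of macrophages alone would lower genes expressed only in macrophages by a common factor. Which members the leukaemic cells also express was not measured. A lower share of macrophages in the Tet2 KO cultures and lower expression within the leukaemic cells therefore cannot be told apart. Mast cells in the Tet2 KO cultures were expected to raise at least 16 of 20 mast cell and basophil markers, with fewer than 10 set as the bound against them. Relative to the median 6 rose, Hpgds and Il1rl1 among them, 8 fell, Cma1 and Mcpt8 among them, and 5 stayed below 1 TPM in every library. That is under the bound of 10 and argues against a rise of this marker set as a whole. The list mixes mast cell and basophil markers, so the count does not decide on mast cells alone. Cells with part of these markers, and an effect of genotype on differentiation, stay open.

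Tet2 stood at nearly the same level in all 4 libraries. If exon 3 reads alone were lost from an unchanged transcript, even coverage would give a log2 change of -0.62. Scaled to the spike-ins, Tet2 changed by -0.2068 (SE 0.0699), more than 2 SE from that value and so outside the bound set for exon loss alone. With scaling to the median and correction for length and GC content it changed by -0.54 (SE 0.0464), within 2 SE. Coverage along the transcript was assumed, not measured, and long transcripts rose in general, so loss of exon 3 alone and a changed transcript level cannot be told apart from gene-level values.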

How the results depend on the processing

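The spike-in and length-corrected scalings were chosen after seeing the data. Of 2227 results of 143 named genes under the alternatives, 2202 kept their side of the threshold and, where they passed it, their direction. A change of sign with no call in either fit counts among these. Another 16 lost and 4 gained a call, and 5 turned (Tet2 under 4 scalings, and Cenpe at -0.155 with the length and GC correction). Leaving out each library gave 7284 to 8037 genes, with the lone library assumed to vary like the others.

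Genes higher and lower numbered 3815 and 3936 under median-ratio scaling (441 and 504 at least 2-fold), 3915 and 3741 under quantile normalization (422 and 482), 3617 and 3597 under spike-in scaling (450 and 499), and 3749 and 4119 with the length and GC correction (412 and 444). Median-ratio and spike-in scaling move the gene median from 0.228 to 0.00231 and 0.0144, whatever its source. Tet2 turned to -0.219, -0.2481, -0.2068 and -0.5433 under the same 4 settings. A pseudocount of 5 left 465 genes at 2-fold (305 higher, 160 lower) and 1 of 0.1 gave 1464 (1040 and 424), since a larger one shrinks the changes of low genes. With an estimated correlation 0 lists passed, and with fry 23. Otherwise the cause was not tested.

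Replicate numbers did not pair the libraries (correlation of deviations -0.0561, from 2 pairs). With the replicate block 8390 genes passed (6179 higher, 2211 lower), 1017 of them 2-fold, with 12 lists, and of the named genes Ass1 lost its call (limma adjusted p = 0.103). The erythroid list gained one (camera adjusted p = 0.0199, and adjusted p = 0.439 with an estimated correlation). Of the 3 splits of the libraries into 2 and 2, the real split gave 8463 genes in limma (8682 unadjusted) and the highest other 0 (6 and 4 unadjusted), and 1 split reached the real value. So few splits cannot give a share under 0.05. Depth is unknown, so its limit could not be set.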

Other observations

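The gene families below were chosen after the data had been seen, so their p-values restate that choice, and none passed with an estimated correlation. The chromosome test was written beforehand.

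Most tested ribosomal protein and aminoacyl-tRNA synthetase genes were higher in Tet2 KO, and most proteasome subunit genes were lower. In the list of MYC targets and ribosome biogenesis, which was fixed beforehand, 9 genes fell and 7 rose (camera adjusted p = 0.0618). Relative to the median of all genes, 17 fell and 5 rose. Myc itself is a member and counts among those that rose, on either scale. Of 76 tested cytosolic ribosomal protein genes, 73 rose and 0 fell, and 48 rose and 3 fell relative to the median of all genes (camera adjusted p = 1.25e-09 over 8 families, and adjusted p = 0.307 with an estimated correlation). Rpl5 rose from 1009 ± 8.61 to 1587 ± 21.4 TPM (n = 2 each). Of 20 aminoacyl-tRNA synthetase genes, 17 rose and 1 fell, or 12 and 3 relative to the median of all genes (camera adjusted p = 0.0041, and adjusted p = 0.307 with an estimated correlation), with Wars up from 46.5 ± 0.0141 to 100.3 ± 3.97 TPM and Sars from 87.1 ± 0.53 to 182.2 ± 6.53 TPM. Of 38 proteasome subunit genes, 26 fell and 2 rose, and 35 fell and 0 rose relative to the median (camera adjusted p = 5.41e-11, and adjusted p = 0.121 with an estimated correlation). Psma2 fell from 298.4 ± 0.361 to 196.2 ± 13.2 TPM. Of 17 V-ATPase subunit genes, one pseudogene included, 9 fell and 1 rose, and 16 fell and 0 rose relative to the median (camera adjusted p = 1.13e-05, and adjusted p = 0.121 with an estimated correlation). Atp6v0d2, a subunit gene of macrophages and osteoclasts, fell from 209.2 ± 9.44 to 30.6 ± 0.891 TPM.

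All 8 tested stefin A genes, which encode cysteine protease inhibitors, fell on either scale (camera adjusted p = 1.41e-11, and adjusted p = 0.121 with an estimated correlation). BC100530 went from 19243 ± 251.8 to 3979 ± 154.6 TPM and Stfa1 from 4579 ± 4.84 to 965.5 ± 47.3 TPM. These are near-identical copies, so the value of each is uncertain. Of 15 circadian clock genes, 14 rose and 1 fell, and 11 rose and 1 fell relative to the median (camera adjusted p = 0.0193, and adjusted p = 0.307 with an estimated correlation). Ciart rose from 4.5 ± 0.0849 to 35.8 ± 0.12 TPM, Nr1d2 from 4.21 ± 0.509 to 14.2 ± 1.21 TPM and Dbp from 1.84 ± 0.148 to 7.22 ± 1.37 TPM, and Bhlhe41 fell from 12.2 ± 0.0636 to 4.99 ± 0.318 TPM. Of 289 Zfp zinc finger genes, 205 rose and 6 fell, and 145 rose and 21 fell relative to the median (camera adjusted p = 3.77e-04, and adjusted p = 0.307 with an estimated correlation). Of 47 replication histone genes, 13 fell and 8 rose, or 19 and 6 relative to the median (camera adjusted p = 7.44e-04, and adjusted p = 0.121 with an estimated correlation). These counts are uncertain, since histone genes include near-identical copies, and Hist1h2bq and Hist1h2br had identical values and count as 2 falls. Across genes, which are not independent replicates, the log2 fold change relative to the median had a Spearman correlation of 0.315 with transcript length and of -0.153 with GC content. The family counts above carry no correction for either.

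A hypothesis that a line had gained or lost a whole chromosome was tested on the medians of 20 chromosomes with at least 50 tested genes. The chromosome farthest from the median of all genes was chromosome 18, with 265 genes and a difference of 0.0958, and every one of these chromosomes lay within 0.2. This argues against a whole-chromosome difference between the lines, shared by most cells, for any of these chromosomes. A change common to both lines would not show in this comparison. Chromosome Y was left out of that comparison with 4 tested genes, and its median differed by 0.475, so that a change of Y copies stays open, and a change in few cells or of part of a chromosome was not tested.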
